A study of Mus musculus with 2 samples.

How the data were processed

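Cells of mouse tumours were measured by single-cell RNA sequencing in 2 libraries, 1 from tumours of mice given vehicle and 1 from tumours of mice given mtDSN-2. Tumours were of the MC38 line and resistant to anti-PD-1 per the labels, and the treatments were intratumoral saline with 5% DMSO or mtDSN-2 at 1 mg/kg, every 3 days for 3 doses. The labels state that n = 3 mice or samples were pooled, and give no replicate numbers. Libraries were made from polyA RNA with 10x Genomics 3' chemistry, version 3.1, and sequenced on a NovaSeq 6000, per the labels' protocols. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, written by Cell Ranger 7.0.0 per the file headers. Alignment to mm10 with Cell Ranger 7.0.0 and the use of Seurat 4.3.0 are named in the submitters' processing notes. The gene annotation, the use of intronic reads and the settings of cell calling are not given in the sources used here. No cell labels or clusters came with the files, so all classes below were assigned anew.

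The vehicle library held 12659 barcodes and 183784231 UMIs, with a median of 6238 UMIs and 2413 genes per barcode. The mtDSN-2 library held 9103 barcodes and 92787084 UMIs, with medians of 3403 and 1050. The smallest barcode total was 500 UMIs in both libraries, so shallower cells are missing from both. Cells were kept with at least 200 detected genes, at least 500 UMIs and a mitochondrial share of at most 20%. The gene minimum removed 0 and 215 barcodes (vehicle, then mtDSN-2), and the mitochondrial limit 210 and 415. Doublets were scored with a reimplementation of the Scrublet method with 2 simulated doublets per cell. The highest scores were removed at 0.8% per 1000 barcodes kept, which took 9.96% and 6.92%. The automatic threshold of the method was not used in the main analysis, since it marked 2.08% and 0.220%. After this, 11209 and 8054 cells remained, with medians of 5607 and 3285 UMIs.

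Both libraries were clustered together without integration. Log-normalised values of 2000 variable genes gave 30 principal components, and the Leiden method at resolution 1 on a graph of 15 nearest neighbours gave 27 clusters. A cluster was named from 25 marker sets fixed before the data were examined. The set with most members among the 10 genes with the highest fold over all other cells gave the name, with sets of one cell type joined. Ties, also at 0 members, went to the set with the highest mean log2 fold. At least 3 of its members had to reach 50 CPM at 2 times the level in other cells. The mean log2 fold of the set had to be at least 1. A cluster with no member among those 10 genes was left unnamed if its median depth was under 1/3 of the libraries' median. T-cell-like clusters with raised Foxp3 and a higher score for regulatory than for CD8 markers were called regulatory. Unnamed clusters with under 20 CPM of Ptprc were called Ptprc-low, unless their median depth was that low. The rest are called other unnamed. These limits on naming were set after the files were seen. Names end in "-like" because they rest on markers alone.

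UMIs were summed over the cells of a class in each library and scaled to counts per 1000000 UMIs (CPM). The 7 classes with at least 50 cells in each library were compared by log2 ratios of mtDSN-2 over vehicle with a pseudocount of 1 CPM. With 1 library per group from pooled tumours, no statistical test was made and no p-value is given. Intervals are exact Poisson (UMIs) or Clopper-Pearson (shares) intervals at 95% and cover counting error only. A share of 0 was set against the share that 3 cells would give. Of 46 gene lists fixed before the data were examined, the median log2 ratio of members with at least 20 UMIs over both libraries was compared with 10000 random lists of the same size matched on expression in 20 bins. Percentiles are places among these random lists and are not p-values. Which lists are described for a class was chosen after their values were seen, and the highest and lowest medians of the remaining lists are given under other observations. The median mitochondrial share per cell was taken with no limit on it. For shares of cells with a UMI of a gene and for phase calls, each cell was thinned at random to 1000 UMIs and shallower cells were left out.

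Named genes follow a rule fixed before the data were examined. For each class these are the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with at least 50 CPM in a library and 100 UMIs over both. This ranking leaves out predicted, mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and receptor segment, Xist and Y-linked genes. It also leaves out genes with a level under 0.1 of that in another class of the same library. From each described list up to 4 members with the largest ratios and at least 50 UMIs were named, and 11 genes of immune regulation were always named. The text names part of the genes this rule gives, and some of them are not reported here. Gm42418, S100a8 and S100a9 in other classes, the haemoglobin genes, the Y-linked genes and the genes given for classes found in the mtDSN-2 library alone were chosen after their values were seen. Ranking the genes with the 9 rRNA-like genes left out was also chosen after the data were seen. Gene positions are from GENCODE vM21 on GRCm38 (mm10), where 32235 of 32285 features had a match.

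The computation was tested on simulated counts for the genes of each class, with 200 genes changed by known folds. The median recovered log2 ratios for simulated ratios of 2, 1, -1 and -2 were 1.91, 0.93, -0.94 and -1.77 in Ptprc-low, 1.92, 0.98, -0.97 and -1.94 in macrophage-like, 1.94, 0.95, -1.10 and -1.98 in monocyte-like and 1.78, 0.82, -1.19 and -2.15 in dendritic-cell-like cells. They were 1.93, 0.97, -1.02 and -1.93 in T-cell-like, 1.93, 0.97, -1.01 and -2.02 in regulatory-T-cell-like and 1.95, 0.93, -1.03 and -1.95 in NK-cell-like cells. Counting intervals held the simulated ratio of changed genes in 92 to 100% of cases per fold and class. Of 100 lists of unchanged genes, 1 to 6 per class fell outside the central 95% of random lists.

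Alternatives fixed before the data were examined varied the cell filters, doublet removal, cluster resolution, clustering of each library alone, thinning, the denominator, scaling, weighting of cells, the pseudocount, gene filters and removal of an ambient profile. The ambient profile was the library's sum over all barcodes. Its share of a class was the ratio of class to library CPM ranked 3 from the lowest, among markers of other cell types. These shares were 7.79% to 13.6% in the vehicle and 1.11% to 3.33% in the mtDSN-2 library. Removal was thus unequal, can raise ratios and can leave RNA of other cells in. Alternatives chosen after seeing the data were clustering or scaling without rRNA-like genes, counting only cells of at least 2000 UMIs, and the macrophage-like and T-cell-like clusters most shared by the libraries. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.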

Results

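Tumours of the mouse colon carcinoma line MC38, resistant to antibodies against the inhibitory T cell receptor PD-1, were injected with vehicle or with mtDSN-2, a compound named only by this code in the labels. The series title concerns nanoassemblies that act on mitochondria and on anticancer immunity, so the comparison covers the cell makeup of the tumours and their mitochondrial and immune genes. Each group had 1 library from pooled tumours. No difference therefore has a replicate check, cells are not replicates, and every interval given covers counting error only. Paired values in parentheses are CPM of the class in the vehicle library and then in the mtDSN-2 library, and log2 ratios are of mtDSN-2 over vehicle.

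The libraries differed in their cell makeup. Neutrophil-like cells, marked by the calprotectin genes S100a8 and S100a9, were 0.2498% (0.166 to 0.361) of the cells of the vehicle library and 25.4% (24.4 to 26.3) of those of the mtDSN-2 library, 101-fold higher (28 and 2042 cells). T-cell-like cells were 2.59% (2.30 to 2.90) and 17.8% (16.9 to 18.6), 6.87-fold higher. Cells with almost no transcript of Ptprc, which encodes the leukocyte antigen CD45, were 39.5% (38.6 to 40.4) and 9.93% (9.29 to 10.6), 3.98-fold lower, and were given no cell type because no fixed marker set reached the naming limits in their clusters (highest mean log2 fold 0.48). Macrophage-like cells were 17.2% (16.5 to 17.9) and 6.23% (5.71 to 6.78), 2.75-fold lower, and macrophage- and monocyte-like cells together were 2.86-fold lower (25.8% and 9.01%). The size of these 2 differences depended on the clusters. With each library clustered alone, which gave no monocyte-like cells in the mtDSN-2 library, macrophage-like cells were 23.2% and 20.2%, and with a mitochondrial share of at most 10% they were 14.2% and 2.53%. Cluster 12 (126 and 532 cells, median 893 UMIs), with macrophage markers as its best match, was left unnamed. Thinned to 1000 UMIs before clustering, Ptprc-low cells were 24.0% and 1.47%.

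NK-cell-like cells were 2.32% and 1.38%, 1.68-fold lower in the mtDSN-2 library. Regulatory-T-cell-like cells were 0.776% and 0.944%, dendritic-cell-like cells 1.19% and 0.795%, and B-cell-like cells 0.401% and 0.782%. The counting intervals of the regulatory-T-cell-like and of the dendritic-cell-like shares overlapped. With each library clustered alone, regulatory-T-cell-like cells were 0.785% and 3.36%. Epithelial-like cells, led by the keratins Krt8 and Krt18, were 0 of 11209 cells in the vehicle library, which allows a share of up to 0.0268%, and 0.956% of the mtDSN-2 library, at least 35.7-fold higher. Fibroblast-like cells, led by the collagen genes Col1a1 and Col1a2, were 0 of 11209 and 0.435%, 16.2-fold the share that 3 vehicle cells would give. Neither difference held in every setting. With a mitochondrial share of at most 10%, epithelial-like cells were 0.103% and 1.28%, and thinning to 1000 UMIs before clustering left no such class. Fibroblast-like cells were 0.254% and 2.62% with the automatic doublet threshold and 16.5% and 1.58% after that thinning, where the order turned. Clusters left without a name, mostly of few UMIs, held 27.2% and 32.6%. Among these, cluster 3 (31 and 1427 cells, median 823 UMIs) had the highest score for erythroid genes.

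Monocyte-like cells were 8.59% and 2.78%, but this order turned in 4 of the other settings, among them clustering without rRNA-like genes, where the log2 ratio was 0.82. Haemoglobin transcripts made up 49.8 and 805 CPM over all barcodes. Neutrophil-like cells had a median of 1562 and 2399 UMIs, and 3 of 28 vehicle cells and 599 of 2042 mtDSN-2 cells had under 1000 UMIs. With a minimum of 1000 UMIs their shares were 0.271% and 22.8%. Among cells of at least 2000 UMIs, a threshold chosen after seeing the data, neutrophil-like cells were 3 of 7981 and 1155 of 4974, 618-fold higher with a counting interval of 201 to 3149.9.

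**Figure D1:**
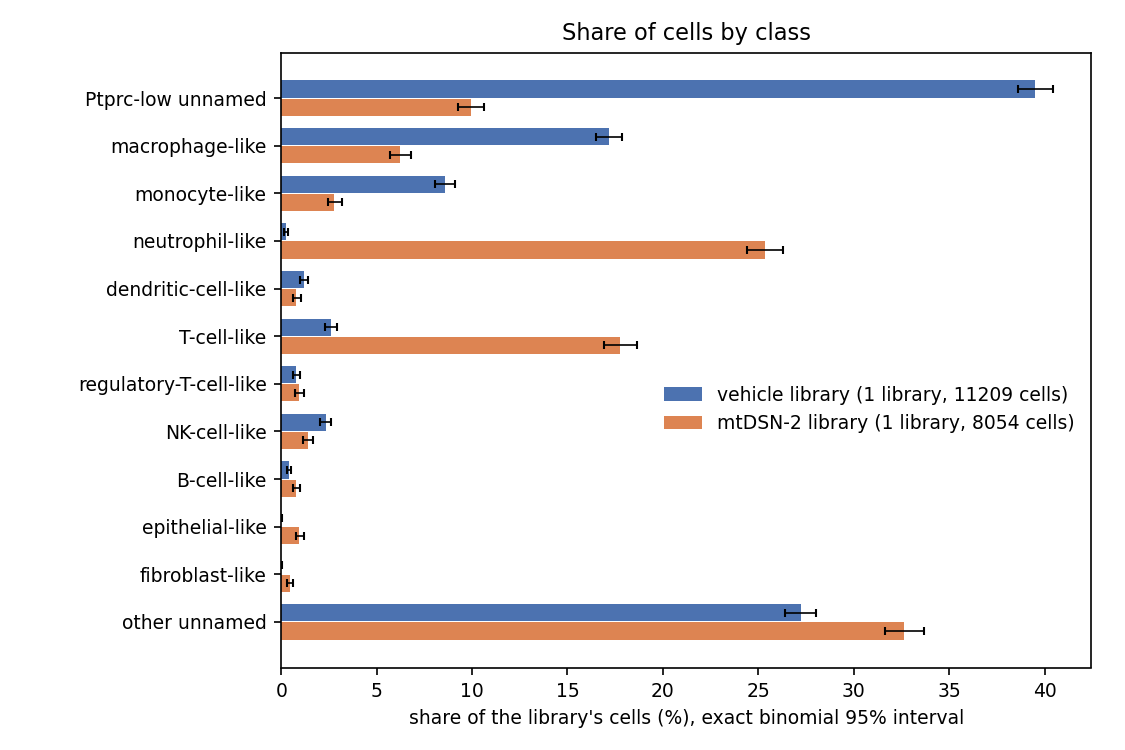
Share of each library's cells (percent, horizontal axis) in each class, with blue bars for the vehicle library and orange bars for the mtDSN-2 library (1 library each); whiskers are exact binomial 95% intervals, which cover counting error only. Neutrophil-like cells were 0.2498% and 25.4%, T-cell-like cells 2.59% and 17.8%, and Ptprc-low cells 39.5% and 9.93%.

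Several gene groups differed in the same direction in all 7 classes with at least 50 cells in each library. Type I interferon response genes, which are switched on by antiviral signalling, were lower in the mtDSN-2 library, with median log2 ratios of -0.88 in Ptprc-low, -0.76 in macrophage-like, -0.67 in monocyte-like, -0.93 in dendritic-cell-like, -0.56 in T-cell-like, -1.54 in regulatory-T-cell-like and -1.01 in NK-cell-like cells. Between 19 of 23 members in monocyte-like and 23 of 23 in macrophage-like cells were lower. Cholesterol synthesis genes were also lower in each class, with medians from -0.83 in Ptprc-low to -2.16 in dendritic-cell-like cells, where 14 of 14 members were lower. G2/M phase genes, which act in cell division, had medians from -0.58 in Ptprc-low to -2.99 in dendritic-cell-like cells. NF-kappaB and tumour necrosis factor response genes, which drive inflammation, were higher in each class, with medians from 0.31 in monocyte-like to 0.97 in NK-cell-like cells. The neutrophil gene S100a8 was also higher in each class, at 1.14 and 33.0 CPM in Ptprc-low, 2.89 and 461 in macrophage-like, 7.17 and 177 in monocyte-like, 2.40 and 82.6 in dendritic-cell-like, 0.730 and 123 in T-cell-like, 0 and 112 in regulatory-T-cell-like and 1.57 and 102 in NK-cell-like cells. The list members Cxcl2 and Il1b stood at 72283 and 10696 CPM in neutrophil-like cells of the mtDSN-2 library. With the ambient profile removed, the NF-kappaB medians ran from 0.13 in monocyte-like to 0.95 in NK-cell-like cells. The removal used a low estimate of RNA from other cells, so neutrophil RNA may remain in these medians. In monocyte-like cells the main median became -0.13 without doublet removal.

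Each of these medians lay outside the central 95% of 10000 random lists of the same size and expression in its class, which describes these libraries and is not a test. With the ambient profile removed, 3 of them came to lie inside: type I interferon genes in T-cell-like cells (median -0.37, percentile 3.76, range -0.40 to 0.13) and, in monocyte-like cells, NF-kappaB (median 0.13, percentile 96.7, range -0.40 to 0.14) and G2/M genes (median -0.40, percentile 17.2, range -0.54 to 0.01). Below, each list is given with its median log2 ratio, its percentile among these random lists and their central range. The median of all genes was itself below 0 under CPM scaling, at -0.13 in Ptprc-low, -0.34 in macrophage-like, -0.34 in monocyte-like, -0.33 in dendritic-cell-like, -0.18 in T-cell-like, -0.13 in regulatory-T-cell-like and -0.11 in NK-cell-like cells. Median-of-ratios scaling moved it to 0.01, -0.02, -0.04, -0.10, -0.03, -0.04 and -0.05 in the same order, so lists are described relative to random lists. In the interferon list, Ifit3, an antiviral effector that shares reads with its near-identical copy Ifit3b, was lower in macrophage-like (200.04 and 18.7), monocyte-like (195 and 40.1) and dendritic-cell-like cells (194 and 12.4). Fdps, an enzyme of the mevalonate pathway that leads to cholesterol, was lower in macrophage-like (41.6 and 8.17), T-cell-like (72.3 and 7.60) and NK-cell-like cells (91.7 and 4.84). Genes whose transcripts contain or resemble ribosomal RNA were far higher in the mtDSN-2 library. Their most abundant member, Gm42418 (ENSMUSG00000098178; chromosome 17, 39846958 to 39848788 in mm10), stood at 4344 and 69175 CPM in macrophage-like cells, and such genes took 0.608% and 10.8% of the UMIs of T-cell-like cells. Cmss1, Gphn, Lars2, Cdk8 and Camk1d, the members within protein-coding genes, were all among the 10 highest genes in T-cell-like, regulatory-T-cell-like and NK-cell-like cells, some of them in Ptprc-low, monocyte-like and dendritic-cell-like cells and none in macrophage-like cells.

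**Figure D2:**
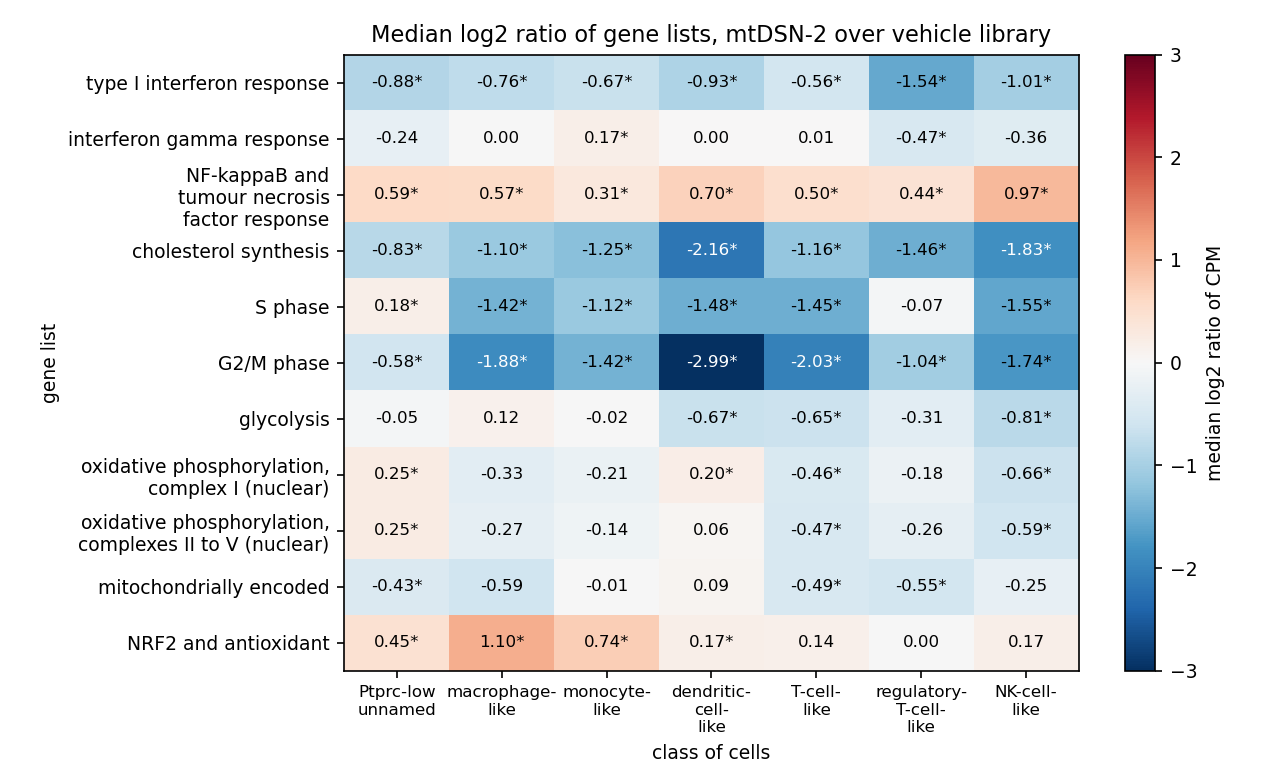
Median log2 ratio of CPM (mtDSN-2 over vehicle library, colour scale and numbers) for 11 gene lists (vertical axis) in 7 classes (horizontal axis), 1 library per group; an asterisk marks medians outside the central 95% of 10000 random lists matched on expression. Type I interferon, cholesterol synthesis and G2/M genes are below 0 in every class shown and NF-kappaB genes above 0, except that the monocyte-like NF-kappaB median turned negative without doublet removal; complex I and complexes II to V in macrophage-, monocyte- and dendritic-cell-like cells also changed sign under other scalings or weights.

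Mitochondrial genes did not differ in one direction across the classes. Nuclear genes of respiratory complex I, which passes electrons from NADH into the respiratory chain, were higher in Ptprc-low cells (30 of 37 members, median 0.25, percentile 99.5, range -0.23 to 0.20) and lower in T-cell-like (31 of 37 members, median -0.46, percentile 0.01, range -0.27 to 0.12) and NK-cell-like cells (36 of 37 members, median -0.66, percentile 0, range -0.22 to 0.29). Nuclear genes of complexes II to V followed the same order, with 32 of 38 members higher in Ptprc-low cells (median 0.25, percentile 97.6, range -0.10 to 0.25), 35 of 38 lower in T-cell-like cells (median -0.47, percentile 0, range -0.26 to 0.14) and 35 of 38 lower in NK-cell-like cells (median -0.59, percentile 0, range -0.26 to 0.32). Examples were Ndufb8 (187 and 293) and Cox7c (475 and 1021) in Ptprc-low cells, Ndufa12 (140.2 and 60.7) and Atp5g1 (239 and 121) in T-cell-like cells, and Ndufs5 (136 and 54.4) and Uqcr11 (202 and 66.5) in NK-cell-like cells. With cells weighted equally, the Ptprc-low medians were 0.14 and 0.16. In regulatory-T-cell-like cells the medians were -0.18 for complex I and -0.26 for complexes II to V, both inside the random ranges (-0.36 to 0.08 and -0.27 to 0.11). In macrophage-like cells they were -0.33 and -0.27, in monocyte-like cells -0.21 and -0.14, and all 4 turned positive under median-of-ratios scaling. In dendritic-cell-like cells they were 0.20 and 0.06, and both turned negative when cells were weighted equally.

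The 13 genes encoded by the mitochondrial genome were lower in Ptprc-low (median -0.43, percentile 0.555, range -0.30 to 0.35), T-cell-like (median -0.49, percentile 1.02, range -0.43 to 0.28) and regulatory-T-cell-like cells (median -0.55, percentile 0.16, range -0.40 to 0.21). In macrophage-like cells 12 of 13 members were lower (median -0.59, percentile 3.87, range -0.62 to 0.28), and in NK-cell-like cells 11 of 13 (median -0.25, percentile 21.0, range -0.51 to 0.50). Medians in monocyte-like and dendritic-cell-like cells were -0.01 and 0.09. Several of these medians shrank under other settings. Thinned to 1000 UMIs they were -0.16 in Ptprc-low, -0.32 in macrophage-like and -0.22 in T-cell-like cells. In Ptprc-low cells the median was -0.18 with cells weighted equally and -0.21 under median-of-ratios scaling. In macrophage-like cells it was -0.11 with a mitochondrial share of at most 10%, and in NK-cell-like cells -0.11 when scaled without rRNA-like genes. With the ambient profile removed, the T-cell-like median came to lie inside the random range (median -0.40, percentile 3.92, range -0.44 to 0.25). The cytochrome c oxidase subunit mt-Co3 was lower in Ptprc-low (3927 and 1909), macrophage-like (4729 and 2293) and T-cell-like cells (4458 and 2814), while mt-Atp8, a subunit of ATP synthase, was higher in Ptprc-low (71.2 and 132), T-cell-like (40.9 and 90.5) and NK-cell-like cells (32.0 and 95.6). With no limit on the mitochondrial share, its median per cell was 3.095% (interquartile range 2.35 to 4.28) and 2.47% (1.78 to 4.18) in Ptprc-low cells, 2.24% and 1.78% in T-cell-like cells, 2.19% and 1.73% in NK-cell-like cells, 1.87% and 1.45% in regulatory-T-cell-like cells and 2.16% and 1.98% in dendritic-cell-like cells. Macrophage-like cells had 2.58% and 2.12%, and over their summed UMIs 2.75% and 2.70%. Monocyte-like cells had 2.09% and 1.50%. These medians come from a clustering of their own, with 2219 and 773 macrophage-like cells.

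Ptprc-low cells of the mtDSN-2 library held more transcripts of chemokines and growth factors that attract myeloid cells (14 of 16 members higher, median 1.26, percentile 100, range -0.44 to 0.22) and, like other classes given below, fewer of extracellular matrix genes (14 of 22 lower, median -0.91, percentile 0, range -0.42 to 0.17). The neutrophil chemokine Cxcl1 was higher (361 and 1134), as were Cxcl2 (56.0 and 188) and the lower expressed Cxcl3 (0.168 and 7.51), Csf3 (0.177 and 3.79) and Csf2 (0.269 and 3.69). With the ambient profile removed, the log2 ratio went from 1.73 to 4.20 for Cxcl2 and from 2.86 to 1.30 for Cxcl3. The profile removed was 8.36% of the UMIs in the vehicle and 2.235% in the mtDSN-2 library, so this unequal removal can itself raise a ratio. The neutrophil gene S100a8 stood at 1.14 and 33.0 CPM in the same cells, and Cxcl2 at 72283 CPM in neutrophil-like cells of the mtDSN-2 library. The collagen genes Col5a2 (95.6 and 7.07) and Col6a2 (108 and 18.2) and the matrix protein gene Tnc (36.9 and 5.66) were lower, whereas Loxl2, a collagen-crosslinking enzyme, was higher (1.79 and 16.6). NRF2 and antioxidant genes were higher (16 of 20 members, median 0.45, percentile 100, range -0.40 to 0.20), with Sod2 (72.2 and 184), Txn1 (1051 and 2147), Prdx1 (674 and 1358) and Hmox1 (56.8 and 110.1). Integrated stress response genes were higher as a list (17 of 21 members, median 0.30, percentile 99.53, range -0.38 to 0.23), with the transcription factor Cebpb (94.2 and 251) higher and the serine synthesis enzyme Phgdh (1486 and 553) lower. S phase genes were higher (20 of 30 members, median 0.18, percentile 99.93, range -0.48 to 0.03) while 25 of 34 G2/M genes were lower (median -0.58, percentile 0.14, range -0.44 to 0.06), among them Top2a (411 and 178) and Cenpf (141 and 58.5). The NF-kappaB list had 13 of 17 members higher (median 0.59, percentile 100, range -0.48 to 0.20), and 20 of 23 type I interferon genes were lower (median -0.88, percentile 0.01, range -0.46 to 0.13), such as Trim30a (112 and 43.7) and the RNA sensor Ifih1 (79.5 and 31.6). Of the cholesterol genes 18 of 19 were lower (median -0.83, percentile 0.03, range -0.57 to 0.06), such as Cyp51 (181 and 61.2).

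MHC class II genes were lower in Ptprc-low cells (10 of 10, median -0.87, percentile 0.02, range -0.49 to 0.10), but the median turned to 0.10 once the ambient profile was removed. A further 7 lists lay inside the random ranges, with medians of -0.24 for the interferon gamma response (-0.40 to 0.17), 0.08 for MHC class I presentation (-0.37 to 0.27), -0.11 for the tricarboxylic acid cycle (-0.55 to 0.13), -0.33 for mitochondrial dynamics and mitophagy (-0.51 to 0.15), -0.01 for mitochondrial protein homeostasis (-0.46 to 0.25), -0.41 for DNA and RNA sensing (-0.63 to 0.13) and -0.04 for immunogenic cell death (-0.43 to 0.31). Within these 7, the mitochondrial fusion gene Opa1 (45.3 and 21.6) and Pdia3, an endoplasmic reticulum disulfide isomerase (472 and 241), were lower, and the heat shock gene Hspa1b (109 and 253) was higher. Under median-of-ratios scaling the tricarboxylic acid cycle median became 0.11.

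The genes with the highest ratios in Ptprc-low cells outside the rRNA-like genes were Dhdh (6.76 and 123), the olfactory receptor gene Olfr889 (4.81 and 85.5 CPM, log2 ratio 3.90), Fbxo47 (7.54 and 103 CPM, log2 ratio 3.60) and Fam20b (32.1 and 256 CPM, log2 ratio 2.96), the last encoding a xylose kinase of proteoglycan assembly. Dhdh (ENSMUSG00000011382) lies on chromosome 7, 45470987 to 45488805, Olfr889 (ENSMUSG00000096356) on chromosome 9, 38115198 to 38121245 and Fam20b on chromosome 1, 156678532 to 156719086 in mm10. Those with the lowest were Csmd3 (117 and 2.79 CPM, log2 ratio -4.95), the adrenergic receptor gene Adra1b (52.1 and 0.778 CPM, log2 ratio -4.90), the fatty acid binding protein gene Fabp4 (241 and 7.24 CPM, log2 ratio -4.88) and Calcb (51.1 and 1.12 CPM, log2 ratio -4.62). Alpha-fetoprotein, Afp, was also lower (68.7 and 6.41). For Dhdh the Poisson intervals were 6.76 (6.30 to 7.24) and 123 (120.1 to 127) CPM. Different clusters held these cells: clusters 1, 8, 9, 13 and 16 held most of the vehicle cells, and cluster 10 (35 and 757 cells) most of the mtDSN-2 cells, so each cluster was nearly of 1 library. Median depth was 26097 and 53842 UMIs.

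Summed over the class, macrophage-like cells of the mtDSN-2 library held more transcripts of inflammatory and of suppressive genes. Whether the same cells held both was not tested. Saa3, an acute phase protein, was the gene with the highest ratio (2.15 and 963 CPM, log2 ratio 8.26), followed by the neutrophil chemokine Cxcl3 (13.1 and 1296 CPM, log2 ratio 6.53), the granulocyte growth factor Csf3 (1.63 and 167 CPM, log2 ratio 5.99), Retnla, a marker of alternative activation (2.003 and 172), and the protease inhibitor Slpi (37.4 and 1647). Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826; chromosome 11, 78920787 to 78960254 in mm10), stood at 44.0 (40.5 to 47.7) and 656 (635 to 678) CPM. Arg1, the arginase that competes for the same substrate (ENSMUSG00000019987; chromosome 10, 24915221 to 24927484), stood at 439 (428 to 451) and 2356 (2316 to 2397) CPM. With the arginine transporter Slc7a2 (57.7 and 409) and Arg2 (44.9 and 177), arginine and tryptophan metabolism had 6 of 8 members higher (median 1.44, percentile 100, range -0.72 to 0.31). Also among the highest were Mmp8 (5.34 and 182), Serpinb2 (2.67 and 105), Cd24a (7.42 and 151) and the cytokine Il6 (3.26 and 70.8). The lowest ratios were those of Fcrls (169 and 10.9), Spon1 (147 and 9.81), the histone gene Hist1h1b (84.9 and 6.54), whose reads near-identical histone genes can share, Phgdh (149 and 12.7) and Ifit3 (200.04 and 18.7).

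By list, NRF2 and antioxidant genes were higher in macrophage-like cells (18 of 19 members, median 1.10, percentile 100, range -0.57 to 0.16), with Sod2 (99.5 and 723), the cystine transporter Slc7a11 (98.5 and 684), Gsr (37.0 and 199) and the haem-degrading Hmox1 (373 and 1282). The alternative (M2-type) list had 15 of 19 members higher (median 0.67, percentile 100, range -0.58 to 0.11), including Cd163 (0.371 and 16.9) and Clec10a (2.08 and 25.6), and the inflammatory (M1-type) list 10 of 17 (median 0.33, percentile 99.56, range -0.57 to 0.17), with Ptgs2 (188 and 1373), the prostaglandin synthase, higher and the interleukin-12 subunit Il12b lower (24.1 CPM in the vehicle library against 2 UMIs). Neutrophil activation genes were higher, as in other classes given below (13 of 14, median 1.02, percentile 100, range -0.63 to 0.22), as were lipid handling (10 of 14, median 0.67, percentile 99.99, range -0.59 to 0.18), hypoxia (12 of 19, median 0.24, percentile 99.61, range -0.55 to 0.11) and NF-kappaB genes (14 of 17, median 0.57, percentile 99.98, range -0.57 to 0.21), with Cd36 (81.3 and 357), Hilpda (211 and 771) and Cxcl2 (4978 and 15899) as members. All 23 type I interferon genes were lower (median -0.76, percentile 0, range -0.49 to 0.10), as were 32 of 34 G2/M genes (median -1.88, percentile 0, range -0.57 to -0.10) and 18 of 19 cholesterol genes (median -1.10, percentile 0, range -0.70 to -0.04). Of the interferon gamma response, 11 members were higher and 11 lower, with Gbp2 (144 and 381) higher and the T cell chemokine Cxcl9 (193 and 79.5) lower. Cluster 2 (1524 and 37 cells) held most of the vehicle cells and clusters 11 (396 and 304) and 21 (4 and 161) most of the mtDSN-2 cells. The neutrophil gene S100a8 stood at 2.89 and 461 CPM in this class and S100a9 at 1.34 and 100.4 CPM, whereas S100a9 was the higher of the 2 in neutrophil-like cells of the mtDSN-2 library (15870.2 CPM for S100a8 and 25199.7 CPM for S100a9). Within cluster 11 alone, a restriction chosen after seeing the data, the type I interferon median was -0.25 (percentile 24.6) beside -0.29 for all genes. There hypoxia became -0.49, the M2-type median 0.10, and the log2 ratios of Cxcl9, Cxcl10 and Lpl turned to 0.28, 0.35 and -0.94.

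Monocyte-like cells, all in cluster 6, showed part of the same differences. Saa3 (1.48 and 148 CPM, log2 ratio 5.91), Cxcl3 (19.0 and 340.2 CPM, log2 ratio 4.09), Slpi (129 and 1228), the chitinase-like gene Chil3 (37.7 and 227), Cd24a (19.8 and 121) and Il6 (16.6 and 83.1) were higher. Nos2 (74.2 and 259.5) and Arg1 (395 and 1113) were higher, within arginine and tryptophan metabolism (6 of 8 members, median 0.95, percentile 100, range -0.58 to 0.25), in which Kynu (16.0 and 2.90) was lower. NRF2 genes were higher (15 of 19, median 0.74, percentile 100, range -0.44 to 0.12), with Slc7a11 (199.6 and 655) and Srxn1 (22.1 and 67.7), and so were interferon gamma genes (15 of 22, median 0.17, percentile 99.74, range -0.40 to 0.08), with the guanylate-binding Gbp2 (259 and 678). Lower were Spon1 (298 and 29.0), Hdac9 (145 and 22.2) and Phgdh (182 and 10.1), 19 of 23 type I interferon genes (median -0.67, percentile 0, range -0.40 to 0.08), 18 of 19 cholesterol genes (median -1.25, percentile 0, range -0.74 to -0.07) and 30 of 32 G2/M genes (median -1.42, percentile 0, range -0.70 to -0.15). The NF-kappaB list had 13 of 17 members higher (median 0.31, percentile 99.76, range -0.38 to 0.17), such as Tnfaip2 (213 and 912). With the ambient profile removed, Phgdh went from a log2 ratio of -4.04 to -0.80. Ly6c1, Cd34, Cald1, Fbn1 and Htra1 also ranked lowest, but their log2 ratios turned to 0.59, 0.78, 3.21, 2.74 and 0.77 once the profile of RNA from other cells was removed. That removal took 13.6% of the vehicle and 1.11% of the mtDSN-2 UMIs of this class, so the turned ratios can come from unequal removal.

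Dendritic-cell-like cells, all in cluster 19 (133 and 64 cells), held more transcripts of the lectins Clec10a (18.0 and 179.7 CPM, log2 ratio 3.25) and Cd209a (42.0 and 211 CPM, log2 ratio 2.30), markers of the type 2 conventional subset, and of Tmem176a (39.6 and 165), Tmem176b (49.2 and 190.0) and Sdc4 (65.9 and 256). The interleukin-1 gene Il1b (1916 and 4330.1) and Nfkb2 (61.1 and 128) were higher among the 16 of 17 higher NF-kappaB members (median 0.70, percentile 100, range -0.43 to 0.20). Checkpoint ligands were higher (6 of 10, median 0.32, percentile 98.5, range -0.52 to 0.28; inside the range at 0.24 with the ambient profile removed), with Cd274, which encodes PD-L1, at 457 and 778 CPM. MHC class II genes had a median inside the random range (median 0.25, percentile 92.6, range -0.36 to 0.34), with the class II transactivator Ciita (279 and 130.1) lower and H2-Ab1 (5172 and 7867) higher. Type I interferon genes (22 of 23 lower, median -0.93, percentile 0, range -0.50 to 0.11), cholesterol genes (14 of 14 lower, median -2.16, percentile 0, range -0.91 to 0.00) and G2/M genes (24 of 24 lower, median -2.99, percentile 0, range -0.91 to -0.18) were lower, among them Irf7 (320.1 and 64.0), Msmo1 (86.3 and 4.13) and Top2a (187 and 20.6). The lowest ratios were those of replication-dependent histone genes, which share reads with near-identical copies, and of Ifi213 (176 and 12.4), Tmcc3 (211 and 20.6) and Mtss1 (155 and 12.4). With 64 cells in the mtDSN-2 library, Poisson intervals were 42.0 (29.2 to 58.4) and 211 (172 to 256) CPM for Cd209a. Tmcc3 turned to 0.06 without doublet removal.

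T-cell-like cells, mostly of cluster 4 in both libraries (195 and 1233 cells), had lower levels of genes of division and of energy metabolism. All 30 measured S phase genes were lower (median -1.45, percentile 0, range -0.44 to 0.08), with Rrm2 (66.4 and 15.6) and Cdc6 (24.8 and 2.78), as were 33 of 34 G2/M genes (median -2.03, percentile 0, range -0.38 to 0.08), with Hmmr (80.3 and 8.67) and Tpx2 (114 and 19.3). Glycolysis genes were lower (15 of 16, median -0.65, percentile 0.01, range -0.39 to 0.22), among them lactate dehydrogenase, Ldha (828 and 385), and Pgam1 (245 and 119). Outside the rRNA-like genes the highest ratios were those of S1pr1, the receptor for lymphocyte egress (29.2 and 135), granzyme A, Gzma (149 and 636), the chemokine Ccl5 (1468 and 6158 CPM, log2 ratio 2.07) and the cholesterol exporter Abcg1 (19.7 and 80.5). The lowest were those of Sdc2 (51.1 and 4.60), Fdps, Cd34 (63.5 and 6.64) and Hmmr. RNA from other cells stays open for Sdc2 and Cd34, since the collagen gene Col3a1 was lower too (171 and 38.8). With the ambient profile removed, their log2 ratios were -3.95 and -3.43. For Ccl5 the Poisson intervals were 1405 to 1534 and 6108 to 6209 CPM.

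Activation and co-stimulation genes of T-cell-like cells were higher (10 of 13, median 0.49, percentile 99.92, range -0.48 to 0.24), with the co-stimulatory receptor Cd28 (217 and 462) and Cd40lg (5.11 and 15.1) higher and Tnfrsf4 (118 and 54.5) and Tnfrsf9 (429 and 207) lower. Exhaustion and co-inhibition genes had 11 of 14 members lower, with a median inside the random range (median -0.38, percentile 6.85, range -0.47 to 0.22). Among them were the exhaustion-associated transcription factor Tox (472 and 191), Cd160 (43.8 and 16.2) and Entpd1 (134 and 67.8). Cytotoxic effector genes (median 0.16, percentile 94.3, range -0.39 to 0.21) and naive and memory genes (median 0.17, percentile 94.5, range -0.49 to 0.24) went both ways, with Gzmc (347 and 55.2) and Xcl1 (163 and 46.9) lower and Tcf7 (51.1 and 98.3) higher. NF-kappaB genes were higher (15 of 17, median 0.50, percentile 99.99, range -0.41 to 0.21), such as Tnfaip3 (431 and 834). Type I interferon genes (22 of 23 lower, median -0.56, percentile 0.11, range -0.42 to 0.13) and cholesterol genes (all 19 lower, median -1.16, percentile 0, range -0.61 to 0.11) were lower, with Oasl1 (62.1 and 21.5), but with the ambient profile removed the interferon median became -0.37, inside the random range, and the exhaustion median of -0.50 came to lie outside it (percentile 1.79). Cluster 24 (54 and 51 cells), led by Cd8a, Tox and Pdcd1 among others, held 35.2% and 7.73% of the UMIs of T-cell-like cells. Within cluster 4 alone, a restriction chosen after seeing the data, log2 ratios were -1.29 for Tox, -0.58 for Pdcd1, -0.57 for Cd8a, -0.88 for Gzmc and -1.13 for Cdc6. There the median was 0.29 for NF-kappaB, 0.26 for activation, -0.59 for exhaustion, -0.05 for cytotoxic and -0.10 for naive and memory genes.

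Regulatory-T-cell-like cells, all in cluster 22 (87 and 76 cells), had higher levels of Foxp3, their lineage transcription factor, at 228 (178 to 288) and 423 (364 to 489.6) CPM. Naive and memory genes were higher (9 of 9, median 1.00, percentile 100, range -0.48 to 0.34), with the transcription factors Bach2 (58.6 and 239.6), Satb1 (279.8 and 921) and Lef1 (146 and 293). The list of the regulatory program as a whole lay inside the random range (6 of 13 higher, median -0.12, percentile 48.7, range -0.41 to 0.21), with Areg (296 and 575) and Il10 (198 and 291) higher. Proenkephalin, Penk (524 and 69.8), the interferon-induced Ifit1 (264 and 44.2) and Iigp1 (325 and 102), and Fn1 (335 and 37.2) were lower. All 19 measured type I interferon genes were lower (median -1.54, percentile 0, range -0.43 to 0.18), with Oasl1 (146 and 20.9) and Rtp4 (143 and 32.6). Cytotoxic genes were lower (6 of 9, median -0.59, percentile 0.925, range -0.50 to 0.30), with Ccl5 (1044 and 449). G2/M genes (10 of 12 lower, median -1.04, percentile 0, range -0.51 to 0.27) and all 6 measured cholesterol genes (median -1.46, percentile 0.01, range -0.67 to 0.54) were lower, with Mki67 (172 and 51.2), and NF-kappaB genes were higher (12 of 16, median 0.44, percentile 99.97, range -0.43 to 0.19), with Zfp36 (84.6 and 223). Pdcd1, which encodes PD-1, was lower (137 and 65.1).

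NK-cell-like cells, all in cluster 15 (260 and 111 cells), differed in granzymes, the proteases of cytotoxic granules. Granzyme B, Gzmb, was 1611 (1554 to 1669) and 441 (397 to 489) CPM, 3.64-fold lower. The related Gzmf (6196 and 39.9), Gzmd (4171 and 301), Gzmg (2441 and 33.9) and Gzme (1575 and 93.1) were far lower, although the reads of these near-identical genes cannot be assigned to single members with certainty. Cytotoxic effector genes were lower as a list (12 of 16, median -0.63, percentile 0.38, range -0.49 to 0.39), also with the maturation marker Klrg1 (93.2 and 12.1), and osteopontin, Spp1 (1329 and 95.6), was lower. Naive and memory genes were higher (9 of 10, median 1.24, percentile 100, range -0.61 to 0.47), with the quiescence factor Klf2 (118 and 566) and Tcf7 (44.5 and 123), and Cxcr4 (17.3 and 133), Abcg1 (14.7 and 138) and the chemokine Ccl4 (249.9 and 1206) were also higher. Glycolysis genes were lower (14 of 16, median -0.81, percentile 0, range -0.43 to 0.41), with Ldha (737 and 229.8) and Gapdh (1808 and 791). Dissociation and heat shock genes, which tissue handling can induce, were higher (19 of 21, median 0.69, percentile 99.98, range -0.37 to 0.44), with Hspb1 (32.0 and 156) and Fosb (76.5 and 288). NF-kappaB genes were higher (15 of 17, median 0.97, percentile 100, range -0.41 to 0.43), with Birc3 (105 and 272). Type I interferon (21 of 22 lower, median -1.01, percentile 0, range -0.40 to 0.28), cholesterol (17 of 18 lower, median -1.83, percentile 0, range -0.68 to 0.18) and G2/M genes (28 of 31 lower, median -1.74, percentile 0, range -0.52 to 0.13) were lower, with Isg15 (127 and 31.4), Cyp51 (71.2 and 7.26) and Birc5 (56.0 and 4.84).

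Lists given above for some classes had medians outside the central 95% of random lists in others too. For extracellular matrix genes, lower in all 6 classes where they were measured, these were -1.27 in macrophage-like, -1.47 in monocyte-like, -2.19 in dendritic-cell-like, -1.93 in T-cell-like and -1.88 in NK-cell-like cells. With the ambient profile removed they became 0.90 in monocyte-like and 0 in macrophage-like cells. The unequal removal (13.6% and 1.11% of UMIs in monocyte-like, 10.1% and 3.33% in macrophage-like cells) can itself raise these medians. Neutrophil activation genes were higher, at 0.39 in Ptprc-low, 0.77 in monocyte-like, 0.77 in dendritic-cell-like, 0.39 in regulatory-T-cell-like and 0.68 in NK-cell-like cells. In T-cell-like cells the median of 0.25 was inside the range. Neutrophil RNA may add to these medians and the macrophage-like one, as S100a8 was higher in each class. Naive and memory genes were also higher, at 0.14 in macrophage-like, 0.35 in monocyte-like and 0.76 in dendritic-cell-like cells, although the macrophage-like median became -0.0031 thinned to 1000 UMIs and the monocyte-like one -0.28 without doublet removal. S phase genes were lower, at -1.42 in macrophage-like, -1.12 in monocyte-like, -1.48 in dendritic-cell-like and -1.55 in NK-cell-like cells. Hypoxia genes, higher in macrophage-like cells, were lower at -0.70 in dendritic-cell-like, -0.67 in T-cell-like, -0.46 in regulatory-T-cell-like and -0.67 in NK-cell-like cells, the T-cell-like median becoming -0.12 with the ambient profile removed. MHC class II genes were lower at -1.06 in T-cell-like, -1.14 in regulatory-T-cell-like and -1.59 in NK-cell-like cells. RNA from other cells, estimated higher in the vehicle library, could lower these medians, as in Ptprc-low cells above. It could also lower lipid handling in NK-cell-like and matrix medians in dendritic-, T- and NK-cell-like cells. Myeloid-attracting chemokines were higher at 0.53 in macrophage-like, 0.44 in monocyte-like and 0.52 in dendritic-cell-like cells and lower at -0.70 in T-cell-like and -0.77 in regulatory-T-cell-like cells. Inflammatory (M1-type) genes were higher at 0.33 in Ptprc-low, 0.35 in dendritic-cell-like and 0.49 in NK-cell-like cells and lower at -0.96 in regulatory-T-cell-like cells, although the NK-cell-like median became -0.28 thinned to 1000 UMIs. Cytotoxic genes were lower at -0.90 in macrophage-like and -1.08 in monocyte-like cells, and integrated stress response genes at -0.71 in monocyte-like and -0.47 in T-cell-like cells, but with the ambient profile removed these 4 medians became -0.10, 0.44, -0.05 and 0.03. In dendritic-cell-like cells dissociation and heat shock genes (-1.01), glycolysis (-0.67) and immunogenic cell death genes (-0.61) were lower and NRF2 genes (0.17) higher. In NK-cell-like cells lipid handling (-1.57) and mitochondrial protein homeostasis genes (-0.51) were lower, the latter also in monocyte-like cells (-0.77), where M2-type genes were higher (0.31). In macrophage-like cells activation and co-stimulation (0.55) and MHC class I genes (0.18) were higher, in Ptprc-low cells arginine and tryptophan metabolism (0.33). In regulatory-T-cell-like cells interferon gamma genes were lower (-0.47) and heat shock genes higher (0.17), and in T-cell-like cells the regulatory program was lower (-0.64).

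The 11 genes named in advance were compared in the class where each was highest over both libraries. Cd274 was highest in neutrophil-like cells, at 1558 CPM (1208 to 1979) and 3449 CPM (3397 to 3502). In T-cell-like cells Pdcd1 stood at 196 CPM (173 to 221) and 140.5 CPM (133 to 148), Cd8a, a subunit of the CD8 co-receptor, at 435 CPM (401 to 471) and 293 CPM (282 to 304) and Ifng, the interferon gamma gene, at 320.5 CPM (291 to 352) and 389 CPM (377 to 402). In macrophage-like cells the mannose receptor gene Mrc1 stood at 231 CPM (223 to 239) and 251 CPM (238 to 265), though its log2 ratio was -0.02 in cluster 11 alone. In monocyte-like cells Cxcl9 stood at 425 CPM (407 to 444) and 365 CPM (339 to 392) and Cxcl10, another chemokine for T cells, at 1116 CPM (1086 to 1147) and 1759.6 CPM (1703 to 1818). Other classes went the other way. Cxcl10 was lower in macrophage-like (1309 and 726), T-cell-like (247 and 88.2), regulatory-T-cell-like (524 and 172) and NK-cell-like cells (218 and 108), and Gzmb was higher in T-cell-like cells (811 and 1081). The monocyte-like Cxcl9 order turned under median-of-ratios scaling (log2 ratio 0.10).

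**Figure D3:**
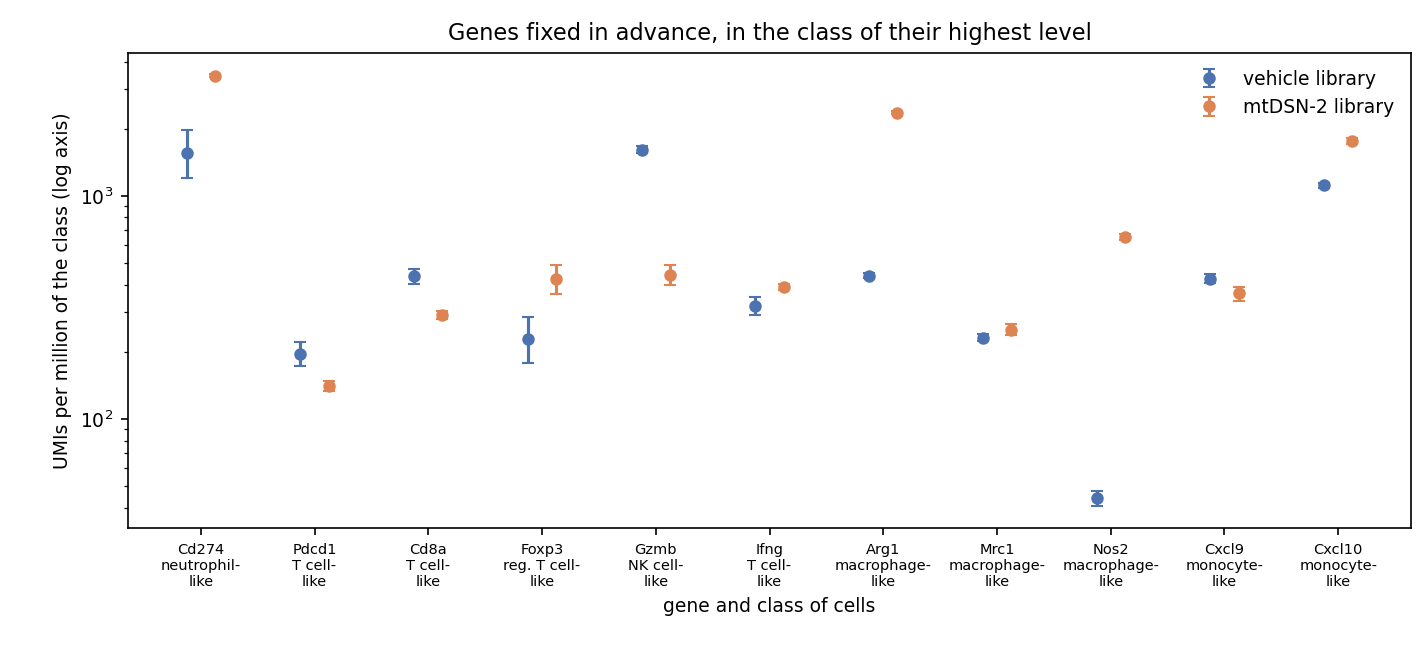
CPM of the class (log axis) for 11 genes fixed in advance, each in the class where it was highest over both libraries (horizontal axis), in the vehicle library (blue) and the mtDSN-2 library (orange), 1 library each; whiskers are exact Poisson 95% intervals, which cover counting error only. In macrophage-like cells Nos2 was 44.0 and 656 CPM and Arg1 439 and 2356 CPM, and in NK-cell-like cells Gzmb was 1611 and 441 CPM. The Mrc1 and Cxcl9 orders turned under other settings. The vehicle value of Cd274 rests on 67 UMIs of 28 neutrophil-like cells, too few for a comparison.

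After each cell was thinned to 1000 UMIs, Nos2 was found in 3.29% (2.53 to 4.19) of macrophage-like cells of the vehicle library and 28.2% (24.3 to 32.4) of those of the mtDSN-2 library. Arg1 was found in 20.9% (19.1 to 22.8) and 55.4% (50.9 to 59.8). In T-cell-like cells, which should lack both genes, the shares were 1.17% and 0.719% for Nos2 and 0.781% and 1.87% for Arg1. Cd274, which no class is known to lack, was found in 22.5% (20.7 to 24.5) and 43.4% (39.0 to 47.9) of macrophage-like cells. Foxp3 was found in 17.4% (10.1 to 27.1) and 36.8% (26.1 to 48.7) of regulatory-T-cell-like cells, with overlapping intervals, against 0 of 4410 and 0 of 781 Ptprc-low cells, which at this depth allows shares of up to 0.0680% and 0.384%. Unthinned, 0.248% and 0.125% of Ptprc-low cells held a Foxp3 UMI. Gzmb was found in 60.8% (54.5 to 66.7) and 26.1% (18.2 to 35.3) of NK-cell-like cells, and in 0.136% and 0.768% of Ptprc-low cells. Intervals of the shares overlapped for Pdcd1 (13.7% and 11.9%), Cd8a (26.2% and 22.0%) and Ifng (16.0% and 21.7%) in T-cell-like cells. In Ptprc-low cells, which should lack them, Pdcd1 was found in 0% and 0%, Cd8a in 0.0907% and 0.256% and Ifng in 0.0227% and 0.128%. Unthinned, the shares were 14.1% and 54.8% for Nos2, 43.4% and 78.5% for Arg1, 59.9% and 82.7% for Cd274, 49.4% and 65.8% for Foxp3, and 88.1% and 55.9% for Gzmb. In T-cell-like cells they were 36.2% and 36.8% for Pdcd1, 57.2% and 63.7% for Cd8a and 37.9% and 52.1% for Ifng. Median depths were 6637 and 9756 UMIs in macrophage-like, 3739.5 and 6234 in T-cell-like, 2846 and 5169.5 in regulatory-T-cell-like, 5914 and 6558 in NK-cell-like and 26097 and 53842 in Ptprc-low cells. Thinning left out 1960 and 1979 cells.

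Phases were called from the S and G2/M lists in the same thinned cells, and no cycling is read from the calls alone. S or G2/M was called for 57.4% and 40.5% of T-cell-like, 45.8% and 32.4% of NK-cell-like, 42.6% and 33.8% of macrophage-like, 38.6% and 18.5% of dendritic-cell-like and 48.8% and 35.5% of regulatory-T-cell-like cells. In Ptprc-low cells it was called for 55.3% and 66.6%, where S phase genes made up 1095 and 1242 CPM and G2/M genes 2857 and 2439 CPM. The corresponding sums in T-cell-like cells were 1709 and 758 CPM for S phase and 4322 and 1883 CPM for G2/M genes. Free RNA from dividing cells could not be told from their own RNA in these calls, and its estimated share differed between the libraries (10.5% and 3.32% of the UMIs of T-cell-like cells).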

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

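No paired analysis was possible because the labels give no replicate numbers, and no test was possible with 1 library per group. Leaving out a replicate would have left a group empty. Values are compared with their counting interval, or, for medians of lists and of cells, with the exact binomial interval of the median. Depth limits the shares, since cells under 500 UMIs are absent and the median depth differed between the libraries. Thinning left out 1960 and 1979 cells at 1000 UMIs and 3228 and 3080 at 2000 UMIs. The T-cell-like, neutrophil-like, Ptprc-low and macrophage-like shares kept their direction in every setting, as did the type I interferon, cholesterol and G2/M medians in all 7 classes. Over all settings, 74 values for shares of cells stayed within the interval, 58 moved beyond it without turning a direction that was clear of counting error, and 7 reversed. For list medians these numbers were 999, 66 and 9 over 88 medians, and for single genes 4078, 1491 and 31 over 550 ratios. Shares of cells with a UMI gave 14, 4 and 0. The cause of each value below, also of each reversal, was not tested.

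In the main analysis the log2 ratio of the share of cells, macrophage-like, was -1.46, and it was -1.99 for Ptprc-low, -1.63 for monocyte-like, 2.78 for T-cell-like and 0.28 for regulatory-T-cell-like cells. The log2 ratio of the share of cells, other unnamed, was 0.26. At cluster resolution 0.5, the log2 ratio of the share was -2.15 for macrophage- and monocyte-like, -1.74 for Ptprc-low and -2.15 for macrophage-like cells. At cluster resolution 2, it was -0.87 for macrophage- and monocyte-like, -0.82 for macrophage-like and -1.17 for monocyte-like cells. With the automatic doublet threshold, it was -0.67 for macrophage- and monocyte-like, -1.69 for Ptprc-low and -1.06 for macrophage-like cells. It was 0.35 for monocyte-like and -0.18 for other unnamed cells (both reversed). With cells of at least 1000 UMIs, it was -0.83 for macrophage- and monocyte-like, -1.72 for Ptprc-low and -0.85 for macrophage-like cells. It was -0.72 for monocyte-like, 3.096 for T-cell-like and 0.77 for other unnamed cells. With cells of at least 500 detected genes, the log2 ratio of the share was -0.94 for macrophage- and monocyte-like cells, -1.68 for Ptprc-low cells, 2.98 for monocyte-like cells (reversed), 3.13 for T-cell-like cells and 0.0032 for other unnamed cells. Clustered without rRNA-like genes (chosen after seeing the data), the log2 ratio of the share was -0.66 for macrophage- and monocyte-like cells, -1.17 for macrophage-like cells, 0.82 for monocyte-like cells (reversed) and 0.0047 for other unnamed cells. With each library clustered alone, it was -0.48 for macrophage- and monocyte-like, -2.16 for Ptprc-low and -0.20 for macrophage-like cells. It was 2.53 for T-cell-like, 2.10 for regulatory-T-cell-like and 0.044 for other unnamed cells. With immune cells alone as the denominator, it was -2.27 for macrophage- and monocyte-like, -2.21 for macrophage-like, -2.38 for monocyte-like and 5.91 for neutrophil-like cells. It was -1.33 for dendritic-cell-like, 2.03 for T-cell-like, -0.47 for regulatory-T-cell-like and -1.50 for NK-cell-like cells. Among cells of at least 2000 UMIs (chosen after seeing the data), the log2 ratio of the share was -1.30 for macrophage- and monocyte-like cells, -1.85 for Ptprc-low cells and -1.34 for monocyte-like cells. It was 9.27 for neutrophil-like, 3.16 for T-cell-like and 1.89 for other unnamed cells. With a mitochondrial share of at most 10%, the log2 ratio of the share was -2.16 for macrophage- and monocyte-like cells, -1.79 for Ptprc-low cells, -2.49 for macrophage-like cells and 0.084 for other unnamed cells. Without doublet removal, the log2 ratio of the share was -0.81 for macrophage- and monocyte-like cells, -1.67 for Ptprc-low cells, -0.75 for macrophage-like cells, -1.15 for monocyte-like cells and -0.088 for other unnamed cells (reversed). With no limit on the mitochondrial share, the log2 ratio of the share was -0.72 for macrophage- and monocyte-like cells, -1.06 for macrophage-like cells, 0.22 for monocyte-like cells (reversed) and -0.044 for other unnamed cells (reversed). Thinned to 1000 UMIs before clustering, it was -2.04 for macrophage- and monocyte-like, -4.03 for Ptprc-low and -2.47 for macrophage-like cells. It was -0.85 for monocyte-like, 3.06 for T-cell-like and 0.89 for other unnamed cells. No monocyte-like class was found in both libraries at cluster resolution 0.5 or with each library clustered alone, so no ratio is given there.

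Under median-of-ratios scaling, the median was -0.41 in macrophage-like cells for type I interferon genes, 0.94 in dendritic-cell-like cells for NF-kappaB genes and -0.77 in macrophage-like cells for cholesterol genes. It was 0.47 in Ptprc-low, 0.026 in macrophage-like (reversed), 0.10 in monocyte-like (reversed) and 0.43 in dendritic-cell-like cells for complex I. It was 0.47 in Ptprc-low, 0.090 in macrophage-like (reversed), 0.18 in monocyte-like (reversed) and 0.30 in dendritic-cell-like cells for complexes II to V and -0.23 in macrophage-like cells for mitochondrially encoded genes. It was 0.29 in Ptprc-low cells for MHC class I, 0.11 in Ptprc-low cells for the tricarboxylic acid cycle, -0.14 in Ptprc-low cells for mitochondrial dynamics, 0.59 in macrophage-like cells for hypoxia and 0.39 in Ptprc-low cells for S phase genes. In the cluster of a class shared most by the libraries alone (chosen after seeing the data), the median was -0.25 in macrophage-like cells for type I interferon genes, 1.24 in macrophage-like cells for NF-kappaB genes, -1.62 in T-cell-like cells for G2/M genes, -0.20 in macrophage-like cells for complex I and -0.27 in macrophage-like cells for mitochondrially encoded genes. It was 0.10 in macrophage-like cells for M2-type genes and -0.49 in macrophage-like cells for hypoxia. With list members of at least 100 UMIs, the median was -1.11 in regulatory-T-cell-like cells for type I interferon genes and -0.82 in monocyte-like and -1.14 in dendritic-cell-like cells for G2/M genes. Without doublet removal, the median was -0.13 in monocyte-like (reversed) and 0.90 in dendritic-cell-like cells for NF-kappaB genes and -0.24 in macrophage-like, -0.10 in monocyte-like and -0.030 in dendritic-cell-like (reversed) cells for complex I. It was -0.0018 in monocyte-like and -0.13 in dendritic-cell-like cells for complexes II to V, -0.15 in dendritic-cell-like cells for mitochondrially encoded genes and 0.31 in Ptprc-low cells for S phase genes. With a pseudocount of 10 CPM, the median was -0.62 in macrophage-like and -0.96 in NK-cell-like cells for cholesterol genes. It was -1.10 in macrophage-like, -0.58 in monocyte-like, -1.47 in T-cell-like and -0.98 in NK-cell-like cells for G2/M genes and -0.97 in T-cell-like cells for S phase genes. Thinned to 1000 UMIs, the median was -3.12 in NK-cell-like cells for cholesterol genes and -0.42 in macrophage-like, -0.32 in monocyte-like, -0.014 in dendritic-cell-like (reversed) and -0.43 in regulatory-T-cell-like cells for complex I. It was 0.15 in Ptprc-low and -0.14 in dendritic-cell-like cells for complexes II to V and 0.31 in Ptprc-low and -1.06 in T-cell-like cells for S phase genes. With a mitochondrial share of at most 10%, the median was -1.20 in macrophage-like cells for G2/M genes, -0.11 in macrophage-like and -0.11 in dendritic-cell-like cells for mitochondrially encoded genes, 0.25 in macrophage-like cells for neutrophil activation and -0.47 in macrophage-like cells for hypoxia. After removal of the ambient profile, the median was -0.40 in monocyte-like cells for G2/M genes, -0.14 in monocyte-like cells for complex I, -0.044 in monocyte-like cells for complexes II to V and 0.10 in Ptprc-low (reversed) cells for MHC class II. With cells weighted equally, the median was 0.14 in Ptprc-low, -0.46 in macrophage-like and -0.21 in dendritic-cell-like (reversed) cells for complex I and 0.16 in Ptprc-low and -0.060 in dendritic-cell-like cells for complexes II to V. It was -0.74 in regulatory-T-cell-like cells for mitochondrially encoded genes and -0.21 in Ptprc-low cells for the tricarboxylic acid cycle. Scaled without mitochondrially encoded and ribosomal protein genes, the median was -0.43 in macrophage-like and -0.57 in T-cell-like cells for complex I and -0.58 in T-cell-like cells for complexes II to V. Scaled without rRNA-like genes (chosen after seeing the data), the median was -0.22 in macrophage-like and -0.087 in monocyte-like cells for complex I and -0.014 in monocyte-like and 0.19 in dendritic-cell-like cells for complexes II to V.

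Single genes turned in 31 cases. Under median-of-ratios scaling, the log2 ratio became 0.022 for Cd274 in Ptprc-low cells and 0.097 for Cxcl9 in monocyte-like cells. After removal of the ambient profile, the log2 ratio became 0.59 for Ly6c1, 0.78 for Cd34 and 3.21 for Cald1 in monocyte-like cells. It became 2.74 for Fbn1 and 0.77 for Htra1 there. In Ptprc-low cells it became 0.68 for Mrc1, 0.47 for Ctss, 0.19 for H2-Eb1, 0.040 for H2-Ab1 and 2.32 for Cd74. In macrophage-like cluster 11 alone (chosen after seeing the data), it became -0.016 for Mrc1, 0.28 for Cxcl9, 0.35 for Cxcl10 and -0.94 for Lpl. Thinned to 1000 UMIs, it became 0.037 for Cxcl9 in monocyte-like and -0.48 for mt-Nd4l, -0.57 for Ndufa1 and -0.35 for Ndufb3 in dendritic-cell-like cells. It became 0.75 for Ndufa5 in regulatory-T-cell-like cells, 1.00 for Nkg7 in regulatory-T-cell-like cells and 0.23 for Ndufa11 in NK-cell-like cells. Without doublet removal, it became 0.18 for Cxcl9 in monocyte-like cells and 0.060 for Tmcc3 in dendritic-cell-like cells. In regulatory-T-cell-like cells it became 0.11 for Gzmb and 0.010 for Nkg7. With cells weighted equally, it became 0.11 for Gzmb in regulatory-T-cell-like cells. With a mitochondrial share of at most 10%, it became -0.26 for Socs1, -1.34 for Egln3 and 0.26 for Pparg in macrophage-like cells.

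With a mitochondrial share of at most 20%, the log2 ratio of the median mitochondrial share was -0.45 in Ptprc-low cells, -0.62 in macrophage-like cells and -0.051 in monocyte-like cells. Over summed UMIs it was -0.029 in macrophage-like cells. Thinned to 500 UMIs, the log2 ratio of the share of cells with a UMI of Arg1 was 1.73 in macrophage-like cells. Thinned to 2000 UMIs, the log2 ratio of the share of cells in S or G2/M phase was -0.80 in macrophage-like cells and -0.83 in T-cell-like cells. In unthinned cells, the log2 ratio of the share of macrophage-like cells with a UMI was 0.46 for Cd274, 0.85 for Arg1 and 1.95 for Nos2.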

Other observations

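The neutrophil-like cells of the mtDSN-2 library held high levels of inflammatory transcripts. The chemokine Cxcl2 stood at 72283 CPM (72045 to 72522), the calprotectin gene S100a8 at 15870 CPM (15758 to 15982), the cytokine Il1b at 10696 CPM (10604 to 10788) and the prostaglandin synthase Ptgs2 at 2428 CPM (2384 to 2472). Arg1 (40.4 CPM (35.0 to 46.5)) and Nos2 (86.2 CPM (78.1 to 94.8)) were far lower there than in macrophage-like cells of the same library. Epithelial-like cells held Krt18 at 668 CPM (630.5 to 707), Krt8 at 658 CPM (621 to 697) and the adhesion gene Epcam at 336 CPM (309.5 to 364), and fibroblast-like cells held Col1a1 at 7872 CPM (7648 to 8102). In Ptprc-low cells Krt18 and Epcam had 0 UMIs in the vehicle library and 16 and 4 UMIs in the mtDSN-2 library. These classes had too few vehicle cells for a comparison within the class.

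The 12 lists not described above had medians that differed less evenly between classes. From the lowest to the highest class, log2 medians were -0.82 to 0.30 for MYC and ribosome biogenesis, -0.68 to 0.22 for ribosomal proteins, -0.92 to 0.03 for endoplasmic reticulum chaperones, -0.58 to 0.14 for lysosome genes and -0.43 to 0.07 for fatty acid oxidation. They were -0.10 to 0.31 for apoptosis and p53, -0.12 to 0.36 for pyroptosis and inflammasome genes, -1.76 to 0.07 for complement and -1.09 to 0.40 for chemokines that attract lymphocytes. TGF-beta and epithelial-mesenchymal transition genes ranged from -0.55 to 0.46 and angiogenesis genes from -0.66 to 0.01. Epithelial adhesion and keratin genes could be compared in Ptprc-low cells alone (0.18).

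Of all differences, 3 patterns were weighed, and the tests for uncalled neutrophils, for neutrophil-like cells under 1000 UMIs, for RNA from other cells in T-cell-like cells, for different clusters of a class, for rRNA-like genes and for host against tumour cells were chosen after the result was seen. The other tests were chosen before their values were computed.

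Neutrophil-like cells made up 0.2498% and 25.4% of cells. A loss of shallow vehicle cells at the UMI minimum is argued against, since 3 of 28 vehicle cells and 599 of 2042 mtDSN-2 cells had under 1000 UMIs, and the difference was 618-fold among cells of at least 2000 UMIs, although that limit leaves 3 vehicle cells and removes more of the shallower vehicle cells. Neutrophils lost in this way, or otherwise in the vehicle suspension but not called as cells, would also leave S100a8 RNA in other classes, yet the median level there was 1.98 against 107 CPM, a ratio of 0.0186. Blood carried into the mtDSN-2 suspension stays open, because haemoglobin RNA was 16.2-fold higher there, and blood or bleeding could likewise add neutrophils. Entry of neutrophils into treated tumours stays open as well and cannot be told from blood with 1 library per group. The higher chemokines of Ptprc-low and macrophage-like cells could be a source for it, although neutrophil RNA in these classes could itself raise Cxcl2.

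Type I interferon genes were lower in the mtDSN-2 library in each class compared. RNA from other cells, at the estimated ambient shares, is argued against in 6 of 7 classes, whose medians stayed under the 2.5th percentile after its removal. It stays open in T-cell-like cells, where the median went from -0.56 (-0.42 to 0.13 among random lists) to -0.37 (-0.40 to 0.13 among random lists, percentile 3.76) because it shrank toward 0. Gene length bias is argued against by length-matched random lists in 7 of 7 classes. Different clusters are argued against in 4 single-cluster classes and in T-cell-like cells of cluster 4 alone (percentile 0.04). They stay open in macrophage-like cells (-0.25, percentile 24.6 in cluster 11 alone) and in Ptprc-low cells, where no cluster held many cells of both libraries. Subset shifts within a cluster stay open. A weaker interferon response after the compound and a difference between the pooled tumours or in sampling time both stay open, since neither could be tested.

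Ptprc-low cells of the libraries fell into separate clusters, with a median of 1.02% of cells of the other library in their cluster. The rRNA-like genes are argued against as the cause, since the median was 1.05% when clustering left them out. Long genes were lower than short genes in Ptprc-low (-0.87), dendritic-cell-like (-0.47), monocyte-like (-0.27) and macrophage-like cells (-0.22) but higher in T-cell-like (0.17), regulatory-T-cell-like (0.22) and NK-cell-like cells (0.71), with a T-cell-like to Ptprc-low ratio of -0.20, which argues against a bias common to the library. Host cells in one library and tumour cells in the other are argued against by Y-linked levels of at most 0.0331 of those in T-cell-like cells in both libraries, which could fit tumour cells without a Y chromosome. An effect of the compound on tumour cells and divergence between separately grown tumours both stay open.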
